A study of Mus musculus with 7 samples.

How the data were processed

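The series holds 7 Affymetrix arrays of sorted CD4+ T cells in 3 groups, B6 (1 array), Sf (3) and Sf.Il2-/- (3). The deposited table gives the authors' intensity for 45037 probe sets in each array, on a linear scale. GCRMA and GCOS are named in the submitters' processing notes, with their versions not stated and no order or parameters. The values differ between arrays in median and upper quartile, so no quantile normalization over the 7 arrays is visible in them. No 2 arrays had identical values in more than 0.535% of probe sets. Correlations over the 11460 genes tested below, on the log2 scale, were 0.933 to 0.988 between Sf arrays and 0.966 to 0.974 between Sf.Il2-/- arrays. Genes are not independent replicates.

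Gene symbols were taken from the array annotation, with 34945 probe sets naming 1 gene, 932 several and 9160 none, and 34741 of the first were brought to current symbols through Entrez numbers. Values were taken as log2(intensity + 1). Each of 18193 genes was represented by its probe set with the highest mean over all arrays among those that name 1 gene, and a gene was tested where the highest of the 3 group means was at least 5 on the log2 scale, which left 11460 genes. In all 303 of 355 list members and 40 of 85 marker genes were tested, and the others were not analysed here. A member not found under its own symbol was looked up through synonyms. By this Gpi1 of the glycolysis list was replaced by a different gene, Pigq, which was tested in its place. Of 169 pairs of a named gene and a comparison, 0 had another probe set past the threshold with the opposite sign.

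Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), in 1 fit of 3 group means over all 7 arrays, with 4 residual and 9.57 total degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The fit estimates the spread from the mutant arrays, and the B6 array is assumed to vary alike. Gene lists (22) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation, and 11 lists of cell type markers formed a family of their own. A list count adjusted over the list alone applies the same adjustment to its members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

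The groups, tests, gene lists, rule for named genes and the first group of other settings were set before the data were examined. The rule named Il2, Foxp3 and Il2ra always. For Sf.Il2-/- v Sf it took the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between groups, and where fewer passed, up to 10 per direction by unadjusted p, said not to pass. For each comparison with B6 it took 10 per direction whose mutant arrays all lay on the same side of the B6 array. It added up to 4 members past the threshold per list and comparison, or the member with the lowest p where none passed. Genes named outside the rule are said to be so, or stand as members in a count or call of a list or in an overlap, as Capg, Ccr8 and Sh2d1a do, or come from the checks of labels and cell types. Of the last, Eif2s3y, S100a8, Cd8a, Cd8b1, Cd74, H2-Aa, H2-Ab1, Itgax, Batf3, Ighm and Jchain were chosen after their values were seen, as was Actl7a.

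Whether replicate numbers pair the arrays was checked by correlating each array's deviation from its group mean with that of the same number in the other mutant group. The correlations were 0.301, 0.211 and 0.505, all above the 0.1 asked for, although 1 array correlated better with another number (0.333). The titles give the numbers and no pairing, so the fit without a block was kept and the replicate block tried as an alternative. The 2 array sets were told apart after the data were examined, by correlation over 14762 dim probe sets (mean log2 under 4), with a lowest correlation of 0.553 within and a highest of 0.554 between sets, so by this measure the sets overlap and the division is uncertain. The upper quartiles were 110 to 116 in set 1 and 130 to 145 in set 2. The sets are not named in the labels.

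On simulated data with the same design and spread, the fit recovered 28.4%, 86.0% and 96.4% of genes changed 2, 4 and 8-fold in Sf.Il2-/- v Sf, 5.07%, 48.7% and 84.8% in Sf v B6, and 4.18%, 60.3% and 83.9% in Sf.Il2-/- v B6. These runs changed 200 of 11460 genes and made 6.2, 4.4 and 3.2 false calls per run. With unchanged genes it made 0.04, 0.02 and 0.04 calls per run. A list shifted by 0.5 was called in 20, 19 and 20 of 20 runs. All of these runs simulated genes as independent, without variation that genes share within an array. The rates therefore need not hold for these data.

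The settings chosen then were no filter or a filter at 6, quantile normalization, arrays centred on their medians, eBayes without a trend, the mean of a gene's probe sets, leaving out each replicate, the 6 mutant arrays alone, the replicate block, an estimated correlation, a 2-fold threshold, and leaving out the chromosome of Il2, markers of other cells or probe sets with IDs ending in x or s. Added after seeing the data were the array set as a block, alone and with quantile normalization, array set 1 alone, a pseudocount of 16, and leaving out the arrays with neutrophil transcripts. The table held 0 Affymetrix control probe sets (AFFX), so the planned check of RNA quality from them was not run. Probe sets with several gene symbols were left out, and those without a symbol were tested separately.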

Results

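RNA of CD4+ T cells from peripheral lymph nodes of male mice aged 3 weeks was measured on Affymetrix mouse arrays, 7 in all. The cells had been enriched by removing B220, CD8, CD11b, CD11c and NK1.1 positive cells and then sorted for CD3 and CD4. B6 mice, the wild type, gave 1 array from RNA pooled from 2 mice. Scurfy mice (Sf), which carry a mutation of Foxp3, the transcription factor that regulatory T cells need, gave 3 arrays. Scurfy mice that also carry a null allele of Il2, the gene of the T cell growth factor interleukin-2, gave 3 arrays and are named Sf.Il2-/- as in the labels. The median intensity per array lay between 29.3 and 32.4 and the upper quartile between 110 and 145. The number of arrays limits the precision, and the comparisons with B6 rest on 1 array assumed to vary like the others. Identities are gene symbols, and the GRCm38.p6 annotation was used only for current symbols and for which genes lie near Il2 or on its chromosome. From their values, not from the labels, the arrays were divided into 2 array sets, which overlap by the correlation used to divide them, with Sf 1, Sf 2, Sf.Il2-/- 1 and Sf.Il2-/- 2 in set 1 and B6, Sf 3 and Sf.Il2-/- 3 in set 2.

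The probe set of Il2 was not lower in the arrays labelled Sf.Il2-/-. Its log2 value was 5.22 in B6, 5.39, 5.09 and 7.35 in Sf, and 7.17, 8.20 and 7.74 in the arrays labelled Sf.Il2-/-. Where its probes lie relative to the disrupted part of the gene is not given, so this value does not test the genotype. The difference from Sf was 1.76 ± 0.53 (log2, SE, n = 3 and 3; limma adjusted p = 0.402), with 2.45 within array set 1 and 0.39 within set 2. Foxp3 read 7.25 in B6, 6.04, 5.87 and 6.32 in Sf, and 4.41, 4.20 and 4.24 in Sf.Il2-/-. Of 2 genes named outside the rule after their values were seen, the Y-linked gene Eif2s3y lay between 9.09 and 10.29 in every array at its brightest probe set, and the neutrophil transcript S100a8 at 6.37 in Sf 1 and 7.63 in Sf.Il2-/- 2, against 2.53 to 4.10 in the other arrays.

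The comparison of Sf.Il2-/- with Sf asks what the lack of IL-2 changes in Foxp3-mutant CD4 T cells. In the arrays labelled Sf.Il2-/-, 6 of 19 tested genes of the regulatory T cell signature and 3 of 30 IL-2 and STAT5 induced genes fell. Il2ra, the alpha chain of the IL-2 receptor, fell by 4.07 ± 0.34 (log2, SE, n = 3 and 3), a 16.8-fold difference (adjusted p = 0.00132), at its brightest probe set. At its other probe set it read 6.79, 6.42 and 7.70 in Sf and 4.93, 4.34 and 5.07 in Sf.Il2-/-, a smaller difference, and over the alternatives its smallest difference was -1.82. Of 2 inhibitors of cytokine signalling, Socs2 fell by 3.15 ± 0.20 (adjusted p = 0.000517) and Cish fell by 1.82 ± 0.25 (adjusted p = 0.0277). The chemokine receptor gene Ccr1 fell by 2.92 ± 0.26 (adjusted p = 0.00212), and Ltb4r1, the gene of a leukotriene B4 receptor, fell by 2.98 ± 0.25 (adjusted p = 0.00132). In all, 32 of 11460 genes changed, 5 higher and 27 lower in Sf.Il2-/-. This balance depended on the arrays, with 667 higher and 201 lower when Sf 3 was left out.

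Among the genes with the largest falls, Cysltr1, a receptor for cysteinyl leukotrienes, fell by 3.18, Adam8, a surface metalloprotease, fell by 2.89, and Plac8 fell by 3.05. Itgae, the alpha E integrin chain that binds E-cadherin, fell by 3.27. Ifitm1, Ifitm2 and Ifitm3, related interferon-inducible membrane proteins, changed by -3.61, -2.62 and -2.68, and AA467197 fell by 3.48. The group with the lower mean read under 4 for Il2ra (3.83), AA467197 (3.35) and Stmnd1 (3.64), near the floor, so their exact sizes are not measured, and the smallest over the alternatives were -1.82, -2.33 and 1.57. The lower mean was also under 5 for Ccr1 (4.02), Klrk1 (4.11), Ltb4r1 (4.13), Socs2 (4.22), Gcg (4.22), Cysltr1 (4.23), Foxp3 (4.28) and Ifitm1 (4.49). Their smallest over the alternatives were -2.14, -1.28, -2.24, -2.34, 2.12, -2.47, -1.26 and -2.93, so these sizes are not exact either. The Ifitm genes are close in sequence, and whether each probe set is specific to its gene was not tested. The 5 genes that rose were Gcg by 2.87, the chemokine gene Ccl4 by 2.74, Stmnd1 by 2.45, the potassium channel gene Kcna2 by 1.57 and the interleukin-1 receptor gene Il1r1 by 1.44. The next genes by unadjusted p, which did not pass, included Ccl5 at 3.40 (adjusted p = 0.0547), Gzmk at 3.25 (adjusted p = 0.0769) and Cxcr5 at 2.02 (adjusted p = 0.099).

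**Figure D1:**
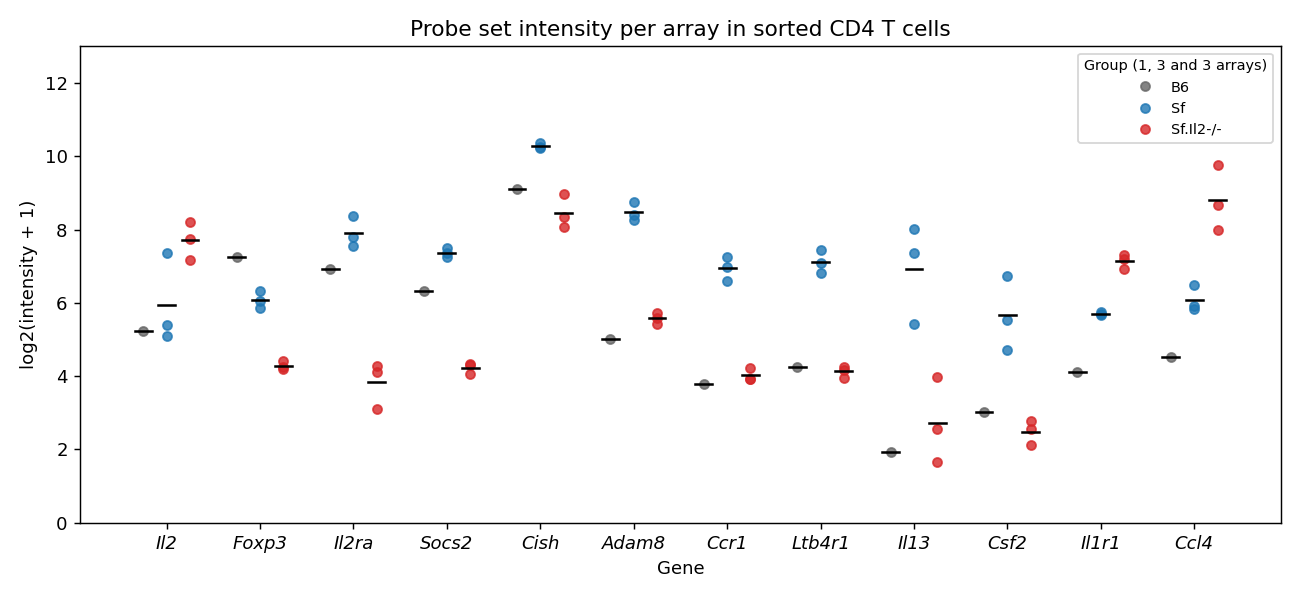
Probe set intensity of 12 genes in each array, as log2(intensity + 1), with points for the arrays of B6 (1), Sf (3) and Sf.Il2-/- (3) and a black bar for each group mean. Il2ra lay between 7.55 and 8.36 in the Sf arrays and between 3.10 and 4.29 in the Sf.Il2-/- arrays.

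The gene lists, fixed beforehand, group these changes. Medians of lists are given as log2 differences minus the median of all tested genes, which was 0.08 in this comparison. Of the 19 tested members of the regulatory T cell signature, 6 fell, 0 rose and 13 did neither, and 6 were also lower when adjusted over the list alone. They were Il2ra, Itgae, Socs2, Ikzf4 (-1.85), Foxp3 (-1.79) and Capg (-1.27). The list as a whole was lower, with a median of -0.44 (adjusted p = 3.44e-10, and adjusted p = 0.131 with an estimated correlation). Of the 30 IL-2 and STAT5 induced genes, 3 fell (Il2ra, Socs2 and Cish), 0 rose and 27 did neither, against 5 lower and 1 higher adjusted over the list alone. This list's median was -0.27 (adjusted p = 1.9e-05, and adjusted p = 0.468 with an estimated correlation). The lists of Th2 genes, chemoattractant receptors, adhesion molecules, and IL-2 and STAT5 induced genes were written with the topic of the study known, so they are not independent of it.

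Of 15 chemoattractant receptors, Ccr1 and Ltb4r1 fell, 0 rose and 13 did neither, against 4 lower and 1 higher adjusted over the list alone (list median -0.22, adjusted p = 0.0221, and adjusted p = 0.468 with an estimated correlation). None of the 12 Th2 cytokines and regulators passed over all genes, while 8 were lower and 1 higher adjusted over the list alone. With the replicate numbers as a block Il13 (adjusted p = 0.00111), Ecm1 (adjusted p = 0.00717), Ccr8 (adjusted p = 0.00804) and Csf2 (adjusted p = 0.045) passed, all lower. That block changes the estimate of the spread and none of the differences. The Th2 list was lower with a median of -1.38 (adjusted p = 3.9e-12, and adjusted p = 0.199 with an estimated correlation). Its member with the lowest p, Csf2, the gene of the growth factor GM-CSF, differed by -3.18 (adjusted p = 0.0547). Il13, named outside the rule after its values were seen, differed by -4.21 (adjusted p = 0.0648), and Il4, named likewise, by -0.91 (adjusted p = 0.848). In Sf.Il2-/- the means of Csf2 (2.48) and Il13 (2.73) were near the floor, so these sizes are not exact, with Csf2 between -3.69 and -1.71 over the alternatives. Among 26 activated and effector memory genes Il2ra fell and the other 25 did not pass, against 4 lower and 1 higher adjusted over the list alone (median -0.21, adjusted p = 0.000927, and adjusted p = 0.468 with an estimated correlation). Of 14 immediate early genes 0 passed and 1 was lower adjusted over the list alone, with Atf3 at -2.13 (adjusted p = 0.149; Sf.Il2-/- mean 3.40, near the floor), and the list median was -0.31 (adjusted p = 0.00479, and adjusted p = 0.468 with an estimated correlation).

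Higher as lists were T follicular helper, interferon response and cholesterol synthesis genes, with 0 members past the threshold over all genes in each. Of 12 T follicular helper genes, 8 were higher adjusted over the list alone, the lowest p being that of Pdcd1, an inhibitory receptor, at 1.32 (adjusted p = 0.0977). That list's median was 0.65 (adjusted p = 6.64e-10, and adjusted p = 0.323 with an estimated correlation). Of 23 interferon response genes 1 was higher adjusted over the list alone, and Oas1a was at 1.10 (adjusted p = 0.197). The interferon list had a median of 0.56 (adjusted p = 2.44e-07, and adjusted p = 0.468 with an estimated correlation). Of 15 cholesterol synthesis genes 1 was higher adjusted over the list alone, and Cyp51 was at 0.85 (adjusted p = 0.252), with a list median of 0.35 (adjusted p = 0.00493, and adjusted p = 0.468 with an estimated correlation). The other 13 lists did not pass, with adjusted p from 0.0955 for cytotoxic genes to 0.958 for adhesion molecules. In them Il1r1 rose and Ahr, the aryl hydrocarbon receptor gene, fell by 1.53 among 7 Th17 genes, Ccl4 rose among 8 chemokines, and Klrk1, the gene of an activating receptor of natural killer cells, fell by 1.88 among 13 cytotoxic genes. For chemokines, adhesion molecules and common gamma chain genes the median, mean and test differed in sign, before and after subtraction of the all-gene median, and for inhibitory receptors after it (median -0.05, tested as higher). Beside these lists, markers of CD4 T cells themselves had a median of 0.48 (adjusted p = 5.28e-07, and adjusted p = 0.629 with an estimated correlation), with 0 of 9 past the threshold and 7 higher adjusted over the list alone.

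In this comparison 908 genes had an unadjusted p under 0.05 by limma. Within array sets 1 and 2 the differences were -3.98 and -4.25 for Il2ra, -3.12 and -3.20 for Socs2 and -1.65 and -2.08 for Foxp3. Fitting the replicate numbers as a block gave 60 genes, including all 32. Each number holds an Sf and an Sf.Il2-/- array, so this block moves none of the differences. It changes only the estimate of the spread, with fewer residual degrees of freedom. Members of the lists added to the calls, beside those of the Th2 list given above, were Ccl5 (adjusted p = 0.0146), Gzmk (adjusted p = 0.0285), Cd68 (adjusted p = 0.0103), Oas1a (adjusted p = 0.045), Pdcd1 (adjusted p = 0.0466), Sh2d1a (adjusted p = 0.039), Ccl1 (adjusted p = 0.0271) and Lgals3 (adjusted p = 0.0103). The array set as a block gave 74 genes (17 higher, 57 lower) and array set 1 alone 571 (352 higher, 219 lower), both including all 32. Without the filter on dim probe sets 11 genes passed, and without the 2 arrays with neutrophil transcripts 49, of which 22 were shared. The count was 11 without Sf 1 (0 higher, 11 lower), 16 without Sf 2 (1 higher, 15 lower) and 868 without Sf 3 (667 higher, 201 lower). The last leaves no Sf array in set 2. It was 13 without Sf.Il2-/- 1 (2 higher, 11 lower) and 8 without Sf.Il2-/- 3 (0 higher, 8 lower). Of the 22 named genes that passed, 5 (Adam8, Ccr1, Ltb4r1, Plac8 and Socs2) stayed past the threshold under every alternative, while Il2ra reached an adjusted p of 0.0908, Foxp3 of 0.0948 and Cish of 0.117 at the highest. Before subtraction of the all-gene median, the list medians of chemoattractant receptors, activated genes and IL-2 and STAT5 induced genes lay above 0 in at least 1 alternative (0.15, 0.03 and 0.04 at the highest). Median differences within array sets 1 and 2, also before subtraction, were -1.39 and -0.97 for Th2 genes, 0.86 and 0.57 for T follicular helper genes, -0.29 and -0.52 for the regulatory T cell signature and 0.88 and 0.23 for interferon response genes. They were 0.03 and -0.52 for IL-2 and STAT5 induced genes, -0.54 and 0.17 for immediate early genes, -0.15 and -0.26 for activated genes, -0.09 and -0.08 for chemoattractant receptors and 0.33 and 0.33 for cholesterol synthesis, with all genes at 0.13 in set 1 and -0.00329 in set 2. The 3 higher and 6 lower lists became 5 and 6 without Sf 1, 3 and 5 without Sf 2, 6 and 3 without Sf 3, 8 and 5 without Sf.Il2-/- 1, and 3 and 5 without Sf.Il2-/- 2. Without Sf 3 activated genes, chemoattractant receptors, IL-2 and STAT5 induced genes and cholesterol synthesis no longer passed, and without Sf.Il2-/- 1 chemoattractant receptors did not. Immediate early genes did not pass without Sf 2 or without Sf.Il2-/- 2, nor cholesterol synthesis without Sf.Il2-/- 2.

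**Figure D2:**
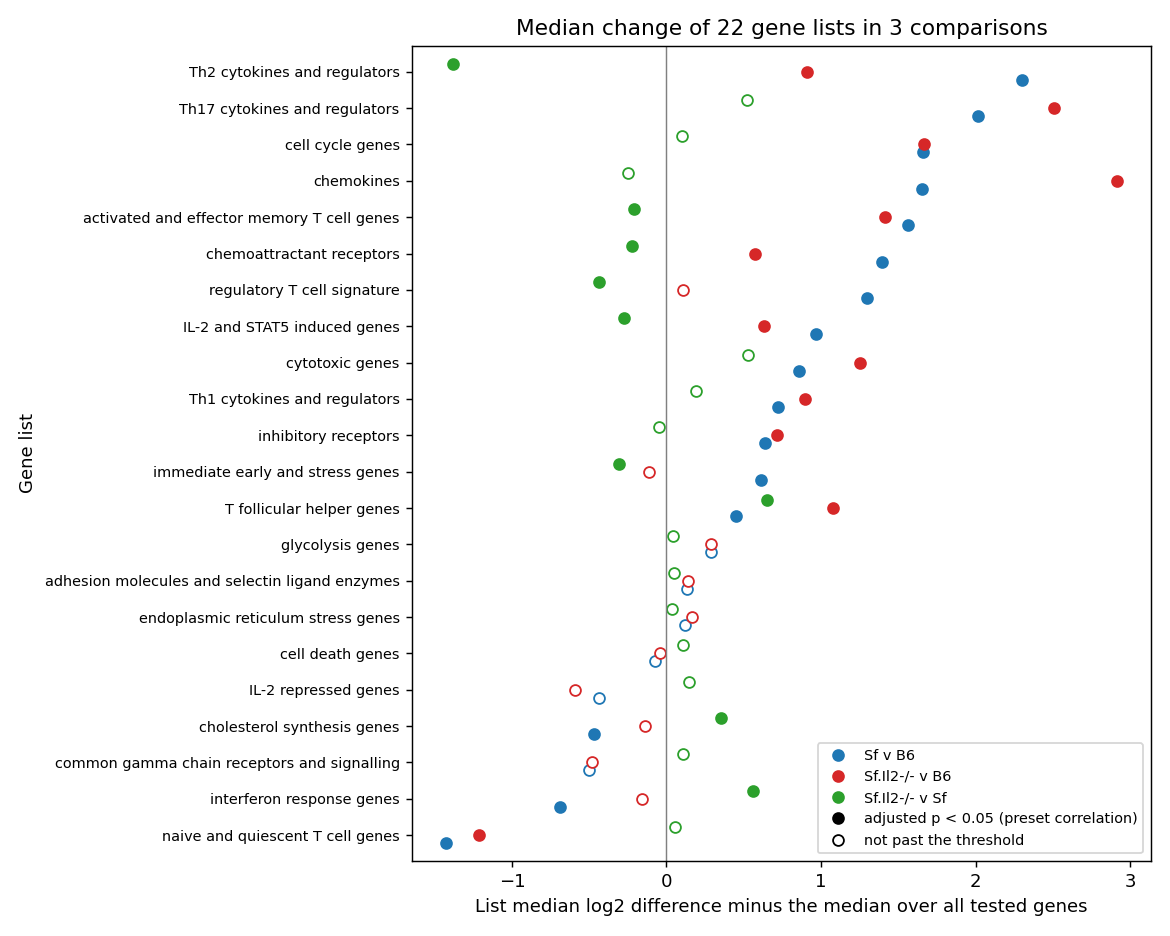
Median log2 difference of 22 gene lists minus the median over all tested genes, for Sf v B6 (blue), Sf.Il2-/- v B6 (red) and Sf.Il2-/- v Sf (green), filled where the list's adjusted p was under 0.05 with the preset correlation. No list passed with an estimated correlation. Th2 genes lay at 2.30 in Sf v B6 and at -1.38 in Sf.Il2-/- v Sf.

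The comparison of Sf with B6 asks what the Foxp3 mutation changes in these cells. Of the activated and effector memory genes tested 11 of 26 rose in Sf, and 8 of 18 naive and quiescent T cell genes fell. Il13, a Th2 cytokine gene, rose by 4.998 ± 1.03 (log2, SE, n = 3 and 1; adjusted p = 0.0402), a size that is not exact, as B6 read 1.94, near the floor, and that lay between 2.91 and 6.17 over the alternatives. Il10, an anti-inflammatory cytokine gene, rose by 3.77 ± 0.49 (adjusted p = 0.00813). Bach2, a repressor active in naive T cells, fell by 2.29 ± 0.32 (adjusted p = 0.0094). Foxp3 itself differed by -1.17 (adjusted p = 0.0904), Il2ra by 0.98 (adjusted p = 0.259) and Il2 by 0.72 (adjusted p = 0.569), none of them past the threshold.

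Altogether 283 genes changed, 150 higher and 133 lower in Sf, with 2584 at an unadjusted p under 0.05 by limma. Among the genes with large rises were Ifitm2 (5.23), Sostdc1 (5.16), Il1r2, a decoy receptor for interleukin-1 (4.52), and Bhlhe40 (4.41). Others read 1.94 to 2.95 in B6, near the floor, so their sizes are not exact and have no order: Il13, Scin (4.54), Pik3ap1 (4.32), the chemokine gene Ccl1 (4.30), Ica1l (4.07) and the inhibitory receptor gene Havcr2 (4.03). Over the alternatives the smallest rise was 2.91 for Il13, 2.81 for Scin, 2.89 for Pik3ap1, 2.81 for Ccl1, 2.45 for Ica1l and 2.10 for Havcr2. Ier3 (3.69) and Ccr1 (3.78), given below, also read under 4 in B6. Il1r1 (4.11), Sostdc1 (4.24), Ltb4r1 (4.24), Il10 (4.42), Nfil3 (4.72), Lif (4.84) and Ifitm2 (4.96) read under 5 there. Their sizes are not exact either. The genes that fell most were Dapl1 (-3.93), A530021J07Rik (-3.67), Sesn1 (-3.10), Oas2 (-3.02), App (-2.97), Ampd1 (-2.91), Vipr1 (-2.86), Arhgap29 (-2.79), Il6ra, the interleukin-6 receptor alpha chain gene (-2.70), and Slc16a5 (-2.66). A530021J07Rik (3.64 to 4.37), App (3.36 to 4.61) and Ampd1 (4.32 to 4.39) read under 5 in every Sf array, so these falls are not exact. The rule for named genes asks that the 3 Sf arrays lie on the same side of the B6 array, and all 283 changed genes met this.

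The all-gene median was -0.25 in this comparison and 0.03 after quantile normalization, so list medians are again given relative to it. Of 26 activated and effector memory genes 11 rose, 0 fell and 15 did neither, with 19 higher adjusted over the list alone. Examples were Havcr2, Lgals3 (3.97), Lag3 (3.03) and S100a6 (2.36), and the list median was 1.57 (adjusted p = 5.28e-21, and adjusted p = 0.0653 with an estimated correlation). Of 12 Th2 genes 4 rose (Il13, Il10, Nfil3 by 3.00 and Maf by 1.85), 0 fell and 8 did neither, with 9 higher and 1 lower adjusted over the list alone (median 2.30, adjusted p = 8.48e-10, and adjusted p = 0.104 with an estimated correlation). Il21 (2.62), Ahr (2.24) and Il1r1 (1.59) rose among 7 Th17 genes, with 5 higher adjusted over the list alone (median 2.02, adjusted p = 1.96e-09, and adjusted p = 0.0653 with an estimated correlation). Of 15 chemoattractant receptors 4 rose (Cxcr6 by 3.44, Ccr1 by 3.16, Ltb4r1 by 2.87 and Ccr2 by 2.12), S1pr1, which guides exit from lymph nodes, fell by 1.94, and 10 did neither. Adjusted over the list alone 7 were higher and 2 lower (median 1.39, adjusted p = 1.86e-05, and adjusted p = 0.201 with an estimated correlation). In the regulatory T cell signature Ebi3 (3.57), Gzmb (3.07) and Entpd1 (1.69) rose and 16 of 19 did not pass, with 8 higher and 1 lower adjusted over the list alone (median 1.30, adjusted p = 1.53e-07, and adjusted p = 0.0653 with an estimated correlation). As background, Ebi3 encodes a cytokine subunit, Gzmb a granule protease and Entpd1 an enzyme that degrades extracellular ATP.

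Of the 8 tested chemokines Ccl1 and Cxcl10 (3.57) rose, with 4 higher adjusted over the list alone (median 1.65, adjusted p = 4.71e-07, and adjusted p = 0.0653 with an estimated correlation). Among 33 cell cycle genes Ccnb2 (2.27) and Rrm2 (1.81) rose and 31 did not pass, but 20 were higher adjusted over the list alone (median 1.66, adjusted p = 1.45e-16, and adjusted p = 0.294 with an estimated correlation). The IL-2 and STAT5 induced genes had 5 of 30 members higher, including Gzmb, Nfil3, Gzma (2.96) and Lif (2.10), and 0 lower, with 12 higher and 2 lower adjusted over the list alone (median 0.97, adjusted p = 1.27e-07, and adjusted p = 0.294 with an estimated correlation). Gzma and Gzmb rose among 13 cytotoxic genes, 6 being higher adjusted over the list alone (median 0.86, adjusted p = 8.41e-05, and adjusted p = 0.309 with an estimated correlation). Of 12 inhibitory receptors Havcr2, Lag3, Pdcd1 (1.92) and Entpd1 rose, with 5 higher and 2 lower adjusted over the list alone (median 0.64, adjusted p = 0.00423, and adjusted p = 0.294 with an estimated correlation). Among 12 T follicular helper genes 3 rose (Il21, Pdcd1 and Icos by 1.42) and Il6ra fell, the same numbers as adjusted over the list alone (median 0.45, adjusted p = 0.0133, and adjusted p = 0.447 with an estimated correlation). In the Th1 list Il12rb1 (1.86) rose and Txk (-1.70) fell out of 14, with 2 higher and 1 lower adjusted over the list alone (median 0.72, adjusted p = 0.0243, and adjusted p = 0.624 with an estimated correlation). Ier3 (3.92) rose among 14 immediate early genes, with 1 higher and 1 lower adjusted over the list alone (median 0.61, adjusted p = 0.0323, and adjusted p = 0.337 with an estimated correlation).

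Lower in Sf were 8 of 18 naive and quiescent T cell genes, with 0 higher and 10 that did neither, and 16 lower adjusted over the list alone. Dapl1, Actn1 (-2.44), Bach2 and S1pr1 fell most, and the list median was -1.43 (adjusted p = 3.03e-10, and adjusted p = 0.104 with an estimated correlation). Among 23 interferon response genes Usp18 (-2.00) and Ifit2 (-1.87) fell, Cxcl10 rose and 20 did neither, with 8 lower and 1 higher adjusted over the list alone (median -0.69, adjusted p = 0.011, and adjusted p = 0.624 with an estimated correlation). Of 15 cholesterol synthesis genes Hmgcs1 (-1.44) fell, and 7 were lower adjusted over the list alone (median -0.47, adjusted p = 0.0113, and adjusted p = 0.337 with an estimated correlation). The other 6 lists did not pass (adjusted p from 0.0694 to 0.999), and before subtraction of the all-gene median, the median, mean and test differed in sign for adhesion molecules, cell death and endoplasmic reticulum stress genes. After it the median of cell death genes still did (-0.07, tested as higher). Some markers of other cells also moved with the group. The dendritic cell list was higher in Sf (median 2.73, adjusted p = 5.66e-05, and adjusted p = 0.451 with an estimated correlation), with Cd74, the invariant chain of MHC class II, up by 3.38 (adjusted p = 0.00166). The CD4 T cell marker list was lower (median -0.66, adjusted p = 0.00483, and adjusted p = 0.617 with an estimated correlation).

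The count and its balance moved with the processing: 555 genes after quantile normalization (392 higher, 163 lower), 849 with arrays centred on their medians (393 higher, 456 lower), 605 with the array set as a block (394 higher, 211 lower), 585 with both block and quantile normalization (440 higher, 145 lower) and 161 without the filter. It was 116 without Sf 1 (84 higher, 32 lower) and 3505 without Sf 3 (711 higher, 2794 lower). Without Sf 3 every Sf array left was in the array set that lacks B6. Of the 56 named genes that passed, 31 stayed past the threshold under every alternative, and the call of Il13 was among those lost, with an adjusted p of 0.0816 at the highest. Of 17 alternatives, immediate early genes passed as a list in 11, Th1 genes in 13 and interferon response genes in 14. B6 lies in set 2 and 2 of the 3 Sf arrays in set 1, so the sets are not balanced here. Within set 2 (1 Sf and 1 B6 array), medians before subtraction were -0.265 for interferon response genes and 0.0326 for immediate early genes. All genes lay at -0.104, Th2 genes at 2.29, activated genes at 1.67 and naive genes at -1.47 there.

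The comparison of Sf.Il2-/- with B6 asks how the double mutant differs from wild type. Of the tested members, 7 of 33 cell cycle genes, 10 of 26 activated and effector memory genes, 5 of 13 cytotoxic genes and 5 of 12 T follicular helper genes rose, and 8 of 18 naive and quiescent genes fell. Gzmk, a granzyme gene, rose by 5.58 ± 0.83 (log2, SE, n = 3 and 1; adjusted p = 0.012) and Pdcd1 by 3.25 ± 0.36 (adjusted p = 0.00263). Foxp3 fell by 2.96 ± 0.32 (adjusted p = 0.00263), Il2ra fell by 3.09 ± 0.48 (adjusted p = 0.014) and Socs2 fell by 2.10 ± 0.29 (adjusted p = 0.00973). The Il2 probe set differed by 2.48 (adjusted p = 0.13), not past the threshold.

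By limma 308 genes changed, 171 higher and 137 lower, with 2129 at an unadjusted p under 0.05. Among the genes with large rises were Sostdc1 (6.01), Gzmk, Il1r2 (5.31), Casp4 (4.37) and Ccl4 (4.28). Others read 1.87 to 2.58 in B6, near the floor, so their sizes are not exact and have no order: Esm1 (6.79), Gcg (5.22), Gab2 (4.54), Pawr (4.42) and Ica1l (4.30), with 4.83, 3.02, 2.44, 2.70 and 2.66 the smallest over the alternatives. The same holds for Havcr2 and Ccl1, given below (smallest 2.01 and 1.17), and for Il2ra, near the floor in Sf.Il2-/- (smallest size -1.46). Foxp3 and Socs2 had means of 4.28 and 4.22 in Sf.Il2-/-, so their sizes are not exact either (smallest -2.275 and -1.49). Nor are those of Il1r1, Sostdc1, Il10 and Ccl4, which read 4.11, 4.24, 4.42 and 4.53 in B6. Among the genes with large falls were A530021J07Rik (-3.62), Dapl1 (-3.29), H2-Ob (-3.14), Slc17a9 (-3.10), Il2ra, St8sia6 (-3.07), Sesn1 (-2.98), H3f3b (-2.97), Foxp3 and Oas2 (-2.90). The all-gene median was -0.14 here, and 0.06 after quantile normalization.

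Of 33 cell cycle genes 7 rose, 0 fell and 26 did neither, with 23 higher adjusted over the list alone. Ccnb2 (2.57), Cdk1 (2.23), Ccna2 (2.13) and Tk1 (2.05) rose most, and the list median was 1.67 (adjusted p = 3.88e-19, and adjusted p = 0.292 with an estimated correlation). Of 26 activated and effector memory genes 10 rose, among them Havcr2 (3.94), Pdcd1 and S100a4 (2.63), Il2ra fell and 15 did neither, with 15 higher and 1 lower adjusted over the list alone (median 1.41, adjusted p = 5.87e-15, and adjusted p = 0.134 with an estimated correlation). Among 13 cytotoxic genes 5 rose, the most changed being Gzmk, Ccl5 (4.01), Gzmb (3.68) and Nkg7 (3.17), also 5 adjusted over the list alone (median 1.25, adjusted p = 3.31e-06, and adjusted p = 0.292 with an estimated correlation). Of 12 T follicular helper genes 5 rose, including Pdcd1, Il21 (3.11) and the chemokine receptor gene Cxcr5 (2.97), and Il6ra fell by 2.61, with 6 higher and 1 lower adjusted over the list alone (median 1.08, adjusted p = 1.09e-07, and adjusted p = 0.246 with an estimated correlation). The chemokines Ccl4, Ccl5, Cxcl10 (3.28) and Ccl1 (2.28) rose out of 8, with 5 higher adjusted over the list alone (median 2.91, adjusted p = 2.14e-07, and adjusted p = 0.101 with an estimated correlation). Il21, Il1r1 (3.03), Batf (2.60) and Rora (2.37) rose among 7 Th17 genes, with 5 higher adjusted over the list alone (median 2.51, adjusted p = 3.86e-10, and adjusted p = 0.101 with an estimated correlation). Of 12 inhibitory receptors 5 rose, including Lag3 (2.54) and Cd160 (1.89), with 5 higher and 1 lower adjusted over the list alone (median 0.72, adjusted p = 9.86e-05, and adjusted p = 0.246 with an estimated correlation).

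Among 12 Th2 genes Il10 (2.89) and Maf (1.84) rose and Ecm1 (-2.61) fell, with 4 higher and 1 lower adjusted over the list alone (median 0.91, adjusted p = 0.00599, and adjusted p = 0.429 with an estimated correlation). Of 15 chemoattractant receptors Cxcr5 and Cxcr6 (2.07) rose and Ccr7 (-1.74) and S1pr1 (-1.68) fell, with 7 higher and 2 lower adjusted over the list alone (median 0.57, adjusted p = 0.00599, and adjusted p = 0.405 with an estimated correlation). In the IL-2 and STAT5 list 4 of 30 rose, among them Gzmb and Gzma (2.66), and 3 fell, among them Il2ra and Socs2, with 7 higher and 5 lower adjusted over the list alone (median 0.63, adjusted p = 0.0134, and adjusted p = 0.651 with an estimated correlation). Eomes (2.52) rose and Txk (-1.50) fell among 14 Th1 genes, with 4 higher and 1 lower adjusted over the list alone (median 0.90, adjusted p = 0.00199, and adjusted p = 0.64 with an estimated correlation). Of 18 naive and quiescent genes 8 fell, 0 rose and 10 did neither, with 12 lower adjusted over the list alone. Dapl1, Bach2 (-2.66), Als2cl (-2.44) and Actn1 (-2.22) fell most (median -1.21, adjusted p = 1.72e-09, and adjusted p = 0.162 with an estimated correlation). The other 10 lists did not pass (adjusted p from 0.0767 to 0.877). In the regulatory T cell signature 4 of 19 rose, including Ebi3 (4.04) and Gzmb, and 3 fell (Foxp3, Il2ra and Socs2), with a median of 0.11 and an adjusted p of 0.319. Before subtraction of the all-gene median, its median, mean and test differed in sign, as did those of immediate early, cell death and endoplasmic reticulum stress genes. After it the medians of immediate early (-0.11) and cell death genes (-0.04) still did, both tested as higher. The dendritic cell marker list was higher here too (median 1.43, adjusted p = 0.000436, and adjusted p = 0.381 with an estimated correlation), with Cd74 up by 3.58 (adjusted p = 0.00172). Only 5 of its 10 markers were tested, and H2-Aa (1.29) and H2-Ab1 (1.435) did not pass. Itgax read 4.72 in B6 and 4.94 to 5.96 in Sf.Il2-/-, and Batf3 4.70 and 4.95 to 5.29.

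Alternatives gave 723 genes after quantile normalization (484 higher, 239 lower), 754 with arrays centred on their medians (442 higher, 312 lower), 721 with the array set as a block (464 higher, 257 lower), 878 with both block and quantile normalization (612 higher, 266 lower) and 138 without the filter. Leaving out 1 array gave 182 genes without Sf 1 (112 higher, 70 lower) and 1513 without Sf 3 (527 higher, 986 lower). The Sf arrays do not enter this difference. Leaving 1 out acts only through the shared estimate of the spread, the filter and the choice of probe set. It gave 126 without Sf.Il2-/- 1 (87 higher, 39 lower), 148 without Sf.Il2-/- 2 (104 higher, 44 lower) and 184 without Sf.Il2-/- 3 (84 higher, 100 lower). The Th2 and chemoattractant receptor lists did not pass after quantile normalization or with arrays centred on their medians. Of the 61 named genes that passed, 31 stayed past the threshold under every alternative.

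The overlap of the comparisons asks whether the lack of IL-2 moved back what had changed in Sf. Of the 150 genes higher in Sf than in B6, 13 were lower in Sf.Il2-/- than in Sf. They were 1500009L16Rik, AA467197, Adam8, Ahr, Ccr1, Cysltr1, Ifitm1, Ifitm2, Ifitm3, Ltb4r1, Niban2, Plac8 and Prxl2a. Of the 133 genes lower in Sf, 0 were higher in Sf.Il2-/- than in Sf, and Il1r1 was the 1 gene higher in both comparisons. The product of the counts over the genes tested gives 0.353 for 13, and simulated unchanged genes gave 0 in each of 50 runs. The product leaves out that the 2 comparisons share the Sf arrays with opposite sign, and the simulation, with 0.04 and 0.02 calls per run, leaves out the changes themselves. Neither gives the number to expect without a reversal, and part of the 13 may come from the shared arrays. Sf and Sf.Il2-/- shared 102 genes higher and 77 lower than B6, where independent calls would share 2.24 and 1.59, with 0 in opposite directions, and both comparisons use the same B6 array, whose part in these numbers cannot be told from 1 array. The 13 became 37 with the array set as a block, 26 with that block and quantile normalization, 20 with quantile normalization, 24 without the arrays with neutrophil transcripts and 6 without the filter. Leaving out an array gave 8 without Sf 1, 519 without Sf 3, 6 without Sf.Il2-/- 1 and 5 without Sf.Il2-/- 3.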

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

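The test described here was added after the tables were opened, on probe sets that the comparisons leave out. Probe sets without a gene symbol are data that no comparison above uses. Of 24435 probe sets passing the same filter, 3205 had no symbol. In Sf.Il2-/- v Sf 24 of the 24435 were past the threshold, and 4 of the 24, all 4 lower, had no symbol. This share is near that of probe sets without a symbol among all tested. Of the 4, the 1 with the lowest p differed by -3.71 (limma adjusted p = 0.00111), with log2 values of 5.67 in B6, 9.70, 8.99 and 8.79 in Sf, and 5.29, 5.45 and 5.62 in Sf.Il2-/-. The next differed by -2.64 (limma adjusted p = 0.00157). Of the rest, 1 read 8.45, 8.61 and 8.20 in Sf and another 8.46, 8.58 and 8.28, so the 4 may not be separate transcripts. Which genes they belong to was not looked up, and no explanation was tested.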

How the results depend on the processing

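The settings with the array set, with array set 1 alone, with the pseudocount of 16 and without the arrays with neutrophil transcripts were chosen after the data were seen. No list or named gene past the threshold changed its tested direction under the settings run, but in Sf.Il2-/- v Sf the median differences of chemoattractant receptors, activated genes and IL-2 and STAT5 induced genes, before subtraction of the all-gene median, reached 0.15, 0.03 and 0.04 at the highest. The 32 genes of Sf.Il2-/- v Sf became 60 with the replicate block, 74 with the array set as a block, 65 with that block and quantile normalization, 571 in array set 1 alone, 49 without the arrays with neutrophil transcripts and 11 without the filter. The 283 of Sf v B6 became 605, 585 with quantile normalization added, 849 with centred arrays, 161 without the filter and 555 with quantile normalization, and the 308 of Sf.Il2-/- v B6 became 721, 878, 754, 138 and 723 in the same order. The 13 genes that moved back became 37, 26 with quantile normalization added, 24 without the arrays with neutrophil transcripts, 6 without the filter and 20 with quantile normalization. Without the filter more genes are tested. For the other settings the cause was not tested. With an estimated correlation 0 lists passed in each of the 3 comparisons, against 9, 16 and 12. Leaving out 1 array at a time gave 8 to 868 genes for Sf.Il2-/- v Sf, 116 to 3505 for Sf v B6, 126 to 1513 for Sf.Il2-/- v B6 and 5 to 519 moved back, the highest always without Sf 3, and 8 to 13, 13 to 17 and 12 to 13 lists. The 3 higher and 6 lower lists of Sf.Il2-/- v Sf became 6 and 3 without Sf 3 and 8 and 5 without Sf.Il2-/- 1. Genes called without Sf 3 were 667 higher and 201 lower in Sf.Il2-/- v Sf. They were 711 and 2794 in Sf v B6, and 527 and 986 in Sf.Il2-/- v B6. Leaving out Sf 3 left Sf with arrays of set 1 only, so its differences then partly mix genotype and array set. The comparison of Sf.Il2-/- with B6 does not use the Sf arrays. It changed only through the shared spread, the filter and the choice of probe set. The 2-fold threshold removed nothing, since all called genes exceed it. Counting each list, called or not, under each setting, the list stayed on its side of the threshold, came past it or lost its call 397, 21 and 22 times in Sf.Il2-/- v Sf, 334, 12 and 28 times in Sf v B6 and 344, 11 and 19 times in Sf.Il2-/- v B6, and named genes, called or not, 772, 71 and 96 times, 842, 10 and 124 times and 882, 15 and 143 times. Genes with low signal over background are left out by the filter, and the limit this sets was not measured otherwise.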

Other observations

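Chosen after the results were seen were the test of the array set, the test of larger differences for the label of Sf 3, and the tests of Cd74, H2-Aa and H2-Ab1. So were the genes Cd8a, Cd8b1, Actl7a, Itgax, Batf3, Ighm and Jchain. The other tests were set after the arrays had been examined and before their own values were seen.

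Cell cycle genes were not past the threshold in Sf.Il2-/- v Sf, but the array sets disagreed. Their median difference was 0.52 within array set 1, with 1 of 33 genes lower, and -0.59 within set 2, with 32 of 33 lower. The difference between the sets was not tested. Of the cell type marker lists, those of CD4 T cells and dendritic cells are given above, and of the others the lowest adjusted p was 0.15 in Sf.Il2-/- v Sf, 0.142 in Sf v B6 and 0.122 in Sf.Il2-/- v B6. The CD8 transcript Cd8a read 7.45 in B6 and 4.37 to 5.01 in the mutants at 1 of its probe sets. Its other probe sets disagreed in size. Those at 7.33 and 7.29 in B6 read 5.50 to 6.67 in the mutants, and those at 6.60 and 5.57 read 2.31 to 3.97. Cd8b1 read 7.30 in B6 and 6.37 to 6.99 in the mutants. The probe set of Actl7a read an intensity of 28881 in Sf.Il2-/- 1 and at most 1202 elsewhere.

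The 27 lower genes of Sf.Il2-/- v Sf are a pattern for which the lack of IL-2 is the biological explanation the design gives. That most called genes were lower did not hold in array set 1 alone (352 higher, 219 lower) or without Sf 3 (667 higher, 201 lower). Without Sf 3 genotype and array set are partly mixed, while within set 1 they are not. A segment of the strain in which the Il2 allele was made would put called genes next to Il2, but 0% of the 32 called genes were among the 100 tested genes nearest to it. Each mutant group has 2 arrays in set 1 and 1 in set 2, so the array set as a block moved none of the differences, and that 32 of 32 genes stayed past the threshold with it is no test of the array set. Of the 10 splits of the 6 mutant arrays, 1, the real one, gave as many as 32 genes, the highest other gave 4, and the other splits that part all 3 same-number pairs gave 0, but 10 splits are too few for a share under 0.05. For lists, 2 of the 10 splits gave as many as the real 9, the highest being 10 with Sf 1, Sf 3 and Sf.Il2-/- 2 together, and each split but the real one puts 2 arrays of a genotype with 1 of the other. The other splits that part all 3 same-number pairs gave 7, 10 and 7 lists, and the rest 0 to 6. The number of lists past the threshold at the preset correlation therefore did not set the real split apart.

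The Il2 probe set was brighter in the arrays labelled Sf.Il2-/- and in Sf 3, for which a wrong label on Sf 3 could be a source. Over the 571 genes called in array set 1 alone, Sf.Il2-/- 3 and Sf 3 differed in the same direction in 397 (69.5%), which missed the 75% asked for as evidence against it and lay above the 40 to 60% asked for as evidence for it. Along that direction the median difference was 0.186 between these 2 arrays, against 0.909 in set 1, so over all 571 genes they differed weakly. Among the 43 of these genes that differed at least 4-fold in set 1, a test added after that, 39 (90.7%) went the same way, just past the bound written for it, with a median difference of 1.84 against 2.63 in set 1. For these larger differences this argues against Sf 3 being an Sf.Il2-/- array, while the test over all 571 genes decided nothing. Il2ra read 8.36 in Sf 3 and at most 4.29 in Sf.Il2-/- at its brightest probe set, and 7.70 and at most 5.07 at the other. Transcripts from the disrupted allele that the probes still detect stay open and were not tested, since the position of the probes is not given.

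Cd74 read 6.37 in B6 and 9.39 to 10.08 in the mutants, and RNA of B cells, macrophages or dendritic cells could be a source, although the depletion of B220, CD11b and CD11c positive cells and the sort for CD3 and CD4 should remove them. Between Sf.Il2-/- and Sf the change of Cd74 exceeded the mean change of H2-Aa and H2-Ab1 by 1.47 (95% interval -0.00656 to 2.95), which holds 0, while in Sf.Il2-/- v B6, on 1 B6 array, it exceeded it by 2.21 (0.125 to 4.30). H2-Aa and H2-Ab1 differed by 2.48 (adjusted p = 0.0947) and 2.79 (adjusted p = 0.0537) in Sf v B6, where the lower of the B cell and macrophage list medians, that of macrophages, was 0.0219 before subtraction of the all-gene median (0.27 after it, and 0.51 for B cells), which decides nothing, as most members lie near the floor. The immunoglobulin transcript Ighm read 5.29 in B6, 9.33, 6.38 and 8.27 in Sf and 6.06 to 6.98 in Sf.Il2-/- at 1 of its probe sets, and 11.53 in B6, 9.92, 9.69 and 10.70 in Sf and 10.81 or more in Sf.Il2-/- at the one in the list, while Jchain read 4.61 in B6, 7.46, 3.98 and 5.53 in Sf and 4.15 to 6.23 in Sf.Il2-/-. The dendritic cell markers Itgax and Batf3 read 4.72 and 4.70 in B6 and 4.80 to 5.96 in the mutants, so they moved less than Cd74. Both RNA of other cells and expression by the mutant T cells, which was not tested, stay open.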
